A study of Mus musculus with 62 samples.

How the data were processed

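Bulk and neuronal RNA of mouse striatum was sequenced in 62 libraries, all of which were used. Per the labels, RNA was extracted with RNeasy kits and libraries were made with a stranded total RNA kit (TruSeq). Per the submitters' processing notes, reads were aligned with STAR to mm10 and counted with HTSeq; versions, and whether strand was used in counting, are not stated. The table deposited by the authors holds raw read counts per gene, whole numbers without normalization, for 48795 Ensembl genes, of which 48349 were matched to a symbol in GENCODE mouse release M21 and 446 were not. Columns were matched to samples by the sample names in the labels, and no column was left over.

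Samples fell into 16 groups by genotype, virus and library kind. Library totals were 49237583 to 101295189 counts for the 31 bulk libraries of the R6/2 series, 8664055 to 11211827 for the 15 bulk libraries of the zQ175 series and 4610476 to 12200813 for the 16 neuronal libraries. A count of 0 allows a level of up to 3 counts, which is 0.0296 to 0.0609, 0.268 to 0.346 and 0.246 to 0.651 CPM in these sets. Such floors cover counting error only. No 2 libraries of a group were identical. Sample numbers were checked for pairing by the correlation across genes of deviations from the group mean. In the zQ175 series the column names call the bulk libraries input and the neuronal ones IP with the same numbers, which points to the same animals, although no label says so. For bulk and neuronal libraries of a group with the same number it averaged 0.151 over 15 pairs, with a range from -0.2 to 0.392, against -0.05 for other numbers. In neuronal N-ZFP libraries all 4 pairs of zQ175 and WT libraries with the same number correlated, at 0.312 to 0.696 (mean 0.532, other numbers -0.174), and libraries 1 and 3 of both genotypes shared a high mitochondrial share, so there the number tracks a shared structure. In no other pair of compared groups did every pair exceed 0.1. As fixed before, groups were compared unpaired, with the replicate number as a block only as an alternative, which is the animal where bulk and neuronal libraries are fitted together.

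Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM normalization, the filterByExpr filter by group, a quasi-likelihood fit with 1 coefficient per group and quasi-likelihood F tests. Adjusted p values are Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. All 8 groups of the R6/2 series shared 1 fit, as did the 4 bulk groups and the 4 neuronal groups of the zQ175 series, and bulk and neuronal libraries were fitted together where they were compared. In all, 19 comparisons were made. They cover genotype under each control virus, each ZFP virus over its Delta virus in each genotype, the differences between these effects, and neuronal over bulk RNA. Folds of genes whose control libraries held 3 counts or fewer in sum are not given.

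Gene lists numbering 23 were written before the data were examined, for striatal and other cell types and for pathways. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members called are counted over all genes tested and adjusted over the list alone. Genes called in the genotype comparisons of the other series were added as lists. They were chosen on samples of this study, so their direction is not independent evidence, although no library was shared. The comparisons, tests, lists, first set of alternatives and naming rule were all fixed before the data were examined. The rule named Htt and a panel (Ppp1r1b, Pde10a, Drd1, Drd2, Adora2a, Penk, Gfap, Slc1a2, Kcnj10 and Aqp4). It also named the 6 highest and 6 lowest called genes with a mean of at least 2 CPM and no overlap between the libraries of the 2 groups. From each list described it took up to 4 members with the smallest p. Predicted genes were left out, and for reversed genes the 10 with the smallest p values were taken. For 4 libraries against 4, no overlap arises by chance in 1 of 35 genes. Genes named outside the rule were chosen after their values were seen.

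Reversed genes are those called between genotypes under Delta and called the opposite way by the ZFP virus in the mutant mice. Because both comparisons use the same Delta libraries, the count was set against 10 simulations of unchanged groups, against independent lists, and against all ways of splitting the Delta libraries 2 and 2. The genotype score of a library is the mean log2 CPM of the genes higher in mutant mice minus that of the lower genes, with an absolute log2 fold change of at least 0.5, from libraries other than those scored. The lists held 1210 higher and 2308 lower genes for N-ZFP in R6/2, 3654 and 4421 for A-ZFP, 607 and 1085 for zQ175 bulk and 554 and 1032 for neuronal libraries. Group means were compared by exact two-sided permutation tests in R. Gene positions, exonic length and GC share were read from GENCODE M21 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.

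Alternatives were DESeq2 size factors, no low-count filter, the Wald test of DESeq2 1.42.0, the replicate number as a block, only the groups compared, and each replicate left out. Scores were also computed on all called genes, on the 100 strongest genes per direction and on another list. Chosen after seeing the data were offsets for transcript length and GC content, the length index as a covariate in the R6/2 series, a refit with the 8 NCAR libraries of the N viruses thinned to the same total, leaving out the 4 neuronal N-ZFP libraries with over 0.3% of counts in mitochondrial protein-coding genes, the pairs of comparisons without shared libraries and the count of N-ZFP genes shared by at least 3 comparisons, with its recount under each alternative. The procedure was tested on simulated data in 7 of the comparisons, each with 100 genes changed 1.5-fold and 100 changed 2-fold. It recovered 66 to 75 of the former and 87 to 95 of the latter in bulk, and 41 to 42 and 77 to 83 in neuronal libraries, with 2 to 15 unchanged genes called. Simulated genes varied independently, and the changed ones were drawn from genes above a set expression level. The simulation thus lacked the structure between libraries seen in the data, so its false calls do not measure those of the real comparisons.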

Results

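RNA was sequenced from mouse striatum in 2 series and summarised as counts per gene in 62 libraries. In the R6/2 series, R6/2 mice, which carry a mutant HTT exon transgene, and NCAR mice received PHP.eB viruses at 4 weeks of age and were collected at 11 weeks. The label NCAR is not expanded and was taken here as animals without the transgene. A-Delta and N-Delta were control viruses, and A-ZFP and N-ZFP carried a working zinc-finger repressor of mutant Huntingtin. The cell-type labels give astrocyte for the A viruses and neuron for the N viruses and were followed here, although the treatment protocol calls the N viruses of the R6/2 series astrocytic, a conflict that bears on each comparison of N with A viruses. In the zQ175 series, zQ175 knock-in mice and WT mice received N-Delta or N-ZFP into the striatum at 6 months and were collected at 12 months, and bulk and neuronal RNA were both sequenced. Each of the 16 groups held 4 libraries, except R6/2 A-ZFP bulk and WT N-ZFP bulk, which held 3. The 31 bulk libraries of the R6/2 series held 49237583 to 101295189 counts each, the 15 bulk libraries of the zQ175 series 8664055 to 11211827, and the 16 neuronal libraries 4610476 to 12200813. Replicates were separate samples per the labels, so the p values measure only the spread between samples. Changes are log2 fold changes ± SE with p values from edgeR adjusted over all genes tested, and a gene is said to rise or fall only where that adjusted p was under 0.05.

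The comparison of R6/2 with NCAR under A-Delta (n = 4 and 4) asked what the transgene changes in striatum given a control virus. Markers of striatal projection neurons fell: 38 of the 45 measured members were lower and none was higher (adjusted p = 0.109 for the list with an estimated correlation). Penk, the enkephalin precursor, changed by -2.05 ± 0.22 (4.14-fold lower, adjusted p = 4.71e-08), and the dopamine receptor genes Drd1 and Drd2 by -1.43 ± 0.16 and -1.51 ± 0.30. Scn4b, a sodium channel subunit, fell from 852 to 79.9 CPM (counts scaled to library size; -3.41 ± 0.33). Interferon-response genes moved the other way, with 26 of 46 higher and none lower (adjusted p = 0.159 with an estimated correlation). Irf7, which encodes a transcription factor of the interferon response, changed by 2.01 ± 0.29 (4.02-fold higher, adjusted p = 6.1e-06). In all, 2974 of 21752 genes rose and 3319 fell, and 392 and 1084 of them changed at least 2-fold. With length and GC offsets 4279 rose and 3291 fell, so which direction held more calls depended on that choice.

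Further neuronal genes fell in the same comparison. Among striatal neuron markers, Rgs4, which limits G-protein signalling, changed by -1.66 ± 0.10, Pcp4 by -1.61 ± 0.12, Itpka by -1.70 ± 0.15 and Ryr1, a ryanodine receptor, by -3.42 ± 0.27. The panel genes Adora2a (-1.83 ± 0.27), Ppp1r1b (-1.86 ± 0.21) and Pde10a (-2.12 ± 0.30) fell as well. Adjusted over the list alone, 41 striatal neuron markers were lower and 1 higher (camera adjusted p = 5.97e-25; adjusted p = 0.109 with an estimated correlation). Of indirect-pathway markers 6 of 13 fell and of direct-pathway markers 5 of 14 fell and 1 rose, with camera adjusted p values of 1.58e-05 and 0.125. The indirect-pathway adjusted p was 0.141 with an estimated correlation. Synaptic signalling genes fell in 35 of 49 cases, among them Gabrd, a GABA-A receptor subunit (-1.68 ± 0.11), and Oprk1, the kappa opioid receptor (-1.82 ± 0.15). Their camera adjusted p was 2.02e-16, with adjusted p = 0.0996 with an estimated correlation. Immediate early genes fell in 21 of 29 cases, with Egr1 at -1.59 ± 0.20 and Dusp1 at -1.80 (camera adjusted p = 9.83e-12; adjusted p = 0.109 with an estimated correlation). Striatal interneuron markers fell in 17 of 20 cases (18 adjusted over the list alone), with Pthlh at -2.02 ± 0.17, Chat, the acetylcholine-synthesising enzyme, at -1.64 ± 0.22 and Npy at -0.95 ± 0.12. That list held with an estimated correlation (adjusted p = 0.00028). Cortical excitatory markers fell in 13 of 23 cases, with Nrgn at -1.13 and Ccn2 at -2.11 (camera adjusted p = 2.06e-06; adjusted p = 0.201 with an estimated correlation).

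Among glial and metabolic groups in the same comparison, 26 of 40 homeostatic astrocyte markers fell and 1 rose. Glul, glutamine synthetase, changed by -0.68 ± 0.09, Mfge8 by -0.76 ± 0.09 and Slc1a2, the main astrocyte glutamate transporter, by -0.70 ± 0.20 (adjusted p = 0.00909). Kcnj10 at -0.73 ± 0.31 (adjusted p = 0.0754), Aqp4 at -0.12 ± 0.10 and Gfap at -0.24 ± 0.19 did not pass the test. The astrocyte list held with an estimated correlation (adjusted p = 0.0296), with 30 lower and 1 higher when adjusted over the list alone. Cholesterol synthesis genes fell in 19 of 27 cases (20 lower and 1 higher adjusted over the list alone), with Fdft1 at -0.94 ± 0.09 (camera adjusted p = 4.39e-10; adjusted p = 0.0831 with an estimated correlation). Oligodendrocyte markers fell in 13 of 30 cases and rose in 1, with Mobp at -0.85 and Tspan2 at -0.83 (camera adjusted p = 0.00019; adjusted p = 0.528 with an estimated correlation). Interferon-response genes were higher in 35 of 46 cases when adjusted over the list alone, including Ifit1 at 1.61 and Usp18 at 2.01 (camera adjusted p = 2.46e-11; adjusted p = 0.159 with an estimated correlation). Developmental transcription factors that adult striatum holds at low levels rose in 17 of 55 cases and fell in none, with Pou4f1 at 5.84 ± 0.54, Wt1 at 3.48 ± 0.51 and Irx5 at 2.24 (adjusted p = 0.0146 with an estimated correlation). Vim, an intermediate filament gene of reactive astrocytes, rose by 0.91 ± 0.14, and 6 of 32 members of the reactive astrocyte list rose and 3 fell (camera adjusted p = 0.399). The remaining lists gave camera adjusted p values of 0.181 for microglia (0 of 30 rose, 4 fell), 0.999 for oligodendrocyte precursors (1 of 18 rose, 2 fell), 0.684 for vascular cells (1 of 30 rose, 1 fell) and 0.926 for ependymal and choroid cells (1 of 18 rose, 2 fell). They were 0.684 for blood (none of 5 changed), 0.147 for clustered protocadherins (9 of 44 rose, 1 fell), 0.147 for nuclear oxidative phosphorylation genes (none of 75 rose, 5 fell), 0.0521 for stress-response genes (11 of 34 rose, 3 fell) and 0.415 for sex-linked genes (1 of 4 rose). Of 13 mitochondrially encoded genes 2 fell (camera adjusted p = 0.0259; adjusted p = 0.591 with an estimated correlation). Among genes that met the naming rule (a mean of at least 2 CPM and no overlap between libraries), the lowest was Abhd11os (ENSMUSG00000085042; mm10 chromosome 5, 135012114 to 135013253, annotated as a transcribed pseudogene), at -5.26 ± 0.26 or 38.4-fold lower. It was followed by Gpr139, an orphan receptor gene, at -3.68. Tmc3 (2.66 ± 0.34), Dmrt2 (2.20) and Tpx2, a spindle assembly factor (2.09 ± 0.14), were the highest by that rule.

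Under N-Delta, R6/2 again differed from NCAR (n = 4 and 4), and striatal neuron markers were lower here too. Penk changed by -1.61 ± 0.21, Drd1 by -1.14, Rgs4 by -1.71 and Abhd11os by -5.70 ± 0.27, and 27 of 45 striatal neuron markers fell while 1 rose (camera adjusted p = 4.55e-06; adjusted p = 0.519 with an estimated correlation). Interferon-response genes rose in 27 of 46 cases and fell in none, with Irf7 at 2.13 and Ddx58 at 1.70 (camera adjusted p = 2.42e-06; adjusted p = 0.445 with an estimated correlation). Nuclear oxidative phosphorylation genes fell in 70 of 75 cases and rose in 1, with Ndufb4 at -1.49 ± 0.19 and Ndufb10 at -0.84, and clustered protocadherins rose in 33 of 44 cases, with Pcdhb21 at 1.40 ± 0.17. The adjusted p was 0.347 with an estimated correlation for each of these 2 lists (camera adjusted p = 7.46e-17 and 1.68e-08). Oligodendrocyte precursor markers rose in 14 of 18 cases, with Gpr17 at 1.31 and Pdgfra at 0.88 (adjusted p = 0.347 with an estimated correlation), and vascular markers in 17 of 30, with Flt1 at 2.15 (adjusted p = 0.519 with an estimated correlation). A length index, the correlation over protein-coding genes between a library's deviation from the mean log2 CPM and transcript length, moved with these groups. It was -0.397 ± 0.077 (SD, n = 4) in NCAR N-Delta and 0.286 ± 0.064 in R6/2 N-Delta, a difference of 0.683 (exact two-sided permutation p = 0.0286, the smallest possible with 4 and 4; adjusted p = 0.114 over 4 tests). In the A-Delta groups the same difference was 0.032 (exact permutation p = 0.943). In all, 5897 genes rose and 6174 fell, and with the length index as a covariate 2249 and 2662 (4911 in place of 12071). Of the A-Delta calls, 1991 higher and 2166 lower genes had the same call under N-Delta and 76 the opposite one. The lowest genes by the naming rule were Pmch (-9.91 ± 1.91, 2 counts in the 4 R6/2 libraries) and Avp (-7.01 ± 1.63), which encode hypothalamic neuropeptides. Both were uneven in NCAR N-Delta, at 27.7 and 19.4 CPM in library 4, 6.73 and 1.43 in library 1 and under 1 in libraries 2 and 3. The 2 control viruses differed in 8057 genes in NCAR and in none in R6/2 by edgeR, where 2154 genes had an unadjusted p under 0.05.

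**Figure D1:**
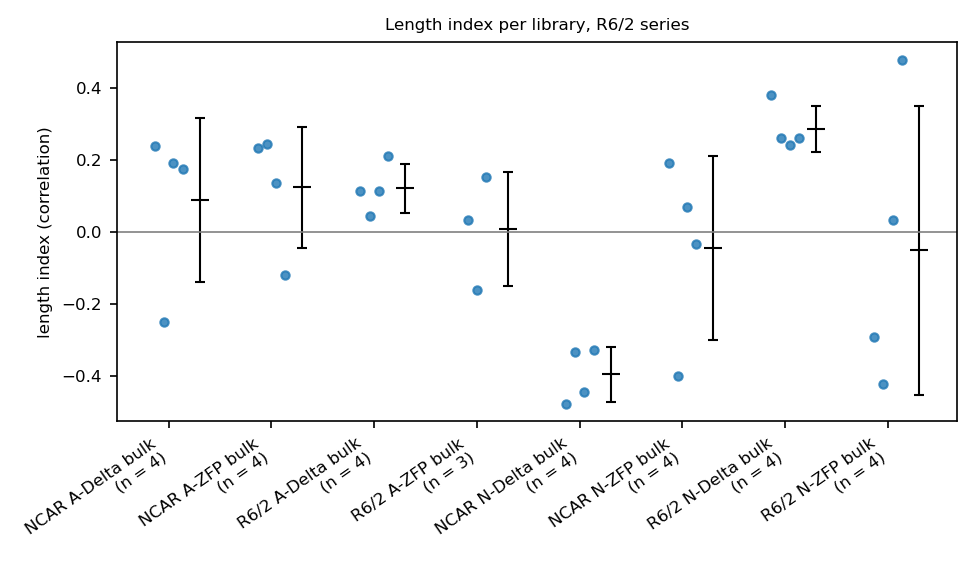
The length index of each bulk library of the R6/2 series (y axis, a correlation without units) by group (x axis), with points for libraries and bars for the mean and SD. The 4 NCAR N-Delta libraries average -0.397 and the 4 R6/2 N-Delta libraries 0.286, while the N-ZFP groups spread from negative to positive values.

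A-ZFP was compared with A-Delta in R6/2 (n = 3 and 4) to find what the repressor directed to astrocytes changes. Gja1, which encodes connexin 43, was the 1 homeostatic astrocyte marker called, higher by 0.43 ± 0.07 (adjusted p = 0.0275), and Lcat, the cholesterol-esterifying enzyme of lipoproteins, rose by 1.04 ± 0.15 (2.06-fold, adjusted p = 0.00106). Lcat lies on chromosome 8 from 105939551 to 105943382. Cd44, a hyaluronan receptor gene, rose by 0.65 ± 0.12 (adjusted p = 0.0291) and Sfrp5, a secreted Wnt inhibitor, by 1.57 ± 0.29. Txlnb fell by 1.59 ± 0.20 (adjusted p = 0.000351), A2m, alpha-2-macroglobulin, by 1.56 ± 0.29 and Itga7, an integrin subunit, by 0.93 ± 0.17. These 7 genes, 4 higher and 3 lower, were all the calls, and 835 genes had an unadjusted p under 0.05. Sfrp5 lies outside the naming rule and was named after its values were seen. Striatal neuron genes did not pass the test, with Penk at -0.17 ± 0.23 and Drd1 at -0.18 ± 0.17. DESeq2 called 21 genes, the fit on the 2 groups alone 2, and the edgeR count was 2, 3, 4 and 3 without R6/2 A-Delta 1, A-Delta 2, A-ZFP 1 and A-ZFP 2. Lcat and Txlnb kept their call in each of these fits, while Gja1, Cd44, Sfrp5, A2m and Itga7 lost it on the 2 groups alone and in several omissions.

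Several groups moved together under A-ZFP in R6/2 although few members passed the test one by one. For homeostatic astrocyte markers 1 of 40 rose over all genes, 6 rose and none fell adjusted over the list alone, and the list held with an estimated correlation (camera adjusted p = 1.51e-17; 0.00425 with an estimated correlation). Clu, an abundant astrocyte lipoprotein gene (0.35 ± 0.08), and Aqp4, the astrocyte water channel (0.42 ± 0.11), were among the 6. Reactive astrocyte genes gave 5 of 32 higher adjusted over the list alone, with Gfap at 0.89 ± 0.20 and Gbp2 at 1.25, and 1 over all genes (camera adjusted p = 4.5e-06; 0.0249 with an estimated correlation). Endoplasmic reticulum and other stress-response genes gave 5 of 34 higher over the list alone and none over all genes, with Sdf2l1 at 0.56 ± 0.11, Hspa5, the chaperone BiP, at 0.35 and Xbp1 at 0.30 (camera adjusted p = 5.73e-13; 0.00393 with an estimated correlation). Interneuron markers gave 2 of 20 higher over the list alone, Npy at 0.44 and Sst at 0.45 (camera adjusted p = 1.19e-10; 0.000555 with an estimated correlation). Interferon-response genes (8 of 46 higher over the list alone) and cholesterol synthesis genes (none of 27) gave camera adjusted p values of 4.9e-10 and 1.81e-09. These became adjusted p = 0.357 and adjusted p = 0.111 with an estimated correlation. Striatal neuron markers had a median of -0.20 with none of 45 called (camera adjusted p = 4.83e-06; adjusted p = 0.71 with an estimated correlation).

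In NCAR (n = 4 and 4) A-ZFP lowered 4 genes and raised none by edgeR, and 544 genes had an unadjusted p under 0.05. Fitted on the 2 groups alone 2 rose and 2 fell, and DESeq2 called 1 higher and 4 lower. Txlnb (chromosome 10, 17796226 to 17845665) fell by 1.61 ± 0.19 (adjusted p = 6.1e-05) and A2m by 2.27 ± 0.28 (adjusted p = 8.52e-05), as both did in R6/2. Cyp2j6, a cytochrome P450 gene, fell by 0.70 ± 0.10 and Cspg5, a brain proteoglycan gene, by 0.41 ± 0.07. A2m and Txlnb lie outside the naming rule here and were named after their values were seen. The difference between the A-ZFP effects in R6/2 and NCAR reached the threshold for no gene by edgeR or by DESeq2, and 727 genes had an unadjusted edgeR p under 0.05. It was 0.82 ± 0.20 for Lcat and 0.45 ± 0.10 for Gja1 (adjusted p = 0.765 for each) and 0.03 ± 0.26 for Txlnb.

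N-ZFP in R6/2 (n = 4 and 4) raised 15 of 45 striatal neuron markers (adjusted p = 0.576 for the list with an estimated correlation) and 15 of 20 interneuron markers (0.00212). Penk rose by 0.78 ± 0.21 (adjusted p = 0.0146), Drd1 by 0.52 ± 0.15 (0.0274), Ppp1r1b by 0.67 ± 0.21 (0.0325) and Adora2a by 0.86 ± 0.26 (0.0295), while Pde10a at 0.65 ± 0.29 and Drd2 at 0.30 did not pass the test. These 4 lost their call in a fit on the 2 groups alone, and Drd1, Ppp1r1b and Adora2a also without N-ZFP 4 (0.31, 0.47 and 0.57) or single N-Delta libraries. No interneuron marker fell, and those that rose included Pthlh at 1.02 ± 0.17, Chat at 0.93 ± 0.22, Sst at 0.65 and Npy at 0.56. The largest decreases by the naming rule were in Tceal6 (ENSMUSG00000031409, chromosome X, 135208687 to 135210687; -3.54 ± 0.34, 11.7-fold lower), Atp2b3, a plasma membrane calcium pump (-2.98), Nap1l3, a nucleosome assembly protein (-2.97), and Dach1, a transcription regulator (-2.35). In all 1783 genes rose and 1058 fell, and 447 and 133 changed at least 2-fold. With length and GC offsets 1758 rose and 1876 fell, so the excess of increases was not kept.

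Of the 45 striatal neuron markers 15 rose and 1 fell with N-ZFP in R6/2 (19 and 1 adjusted over the list alone). Rasgrp2 rose by 1.20 ± 0.17, Itpka by 0.92 ± 0.15 and Rgs4 by 0.61 ± 0.10, and Arpp21 fell by 1.33 ± 0.21 (camera adjusted p = 0.000109; adjusted p = 0.576 with an estimated correlation). Indirect-pathway markers gave 4 of 13 higher and 1 lower (camera adjusted p = 0.0299; adjusted p = 0.576 with an estimated correlation). The interneuron list held with an estimated correlation (camera adjusted p = 1.1e-08; 0.00212 with an estimated correlation). Synaptic genes rose in 10 of 49 cases, with Oprk1 at 1.45 ± 0.15 and Gabrd at 0.89 ± 0.10, cortical excitatory markers in 8 of 23 and immediate early genes in 4 of 29, with Egr2 at 1.54 and Egr1 at 0.62 ± 0.20. Cholesterol synthesis genes rose in 5 of 27 cases. The adjusted p values with an estimated correlation were 0.576 for the synaptic and immediate early lists and 0.561 for the cortical and cholesterol lists. Nuclear oxidative phosphorylation genes rose in 25 of 75 cases (50 higher and 1 lower adjusted over the list alone), with Ndufb4 at 0.92, and clustered protocadherins fell in 11 of 44, with Pcdhb21 at -0.96 ± 0.17. Each gave adjusted p = 0.561 with an estimated correlation. The length index, which these 2 lists moved with under N-Delta, was -0.051 ± 0.403 (SD) in N-ZFP against 0.286 ± 0.064 in N-Delta of R6/2 (difference -0.337, exact two-sided permutation p = 0.2, n = 4 and 4). Stress-response genes fell in 8 of 34 cases and rose in 2, with Hspa5 at -0.51 ± 0.09 and Xbp1 at -0.25 (camera adjusted p = 0.0433; adjusted p = 0.561 with an estimated correlation). Developmental factors were called in both directions (2 of 55 rose, 4 fell), and Pou4f1 fell by 2.29 ± 0.41 and Wt1 by 1.88 ± 0.44. Gpr139 (2.38 ± 0.28), Cartpt, a neuropeptide precursor (2.31), Fst, follistatin (2.25 ± 0.21), and Hrh3, the histamine H3 receptor (1.96 ± 0.24), were the highest by the naming rule. The count of 2841 called genes was 712 in a fit on the 2 groups alone. It was 1627, 1746 and 1710 without N-Delta 1, 2 and 4, 1407 and 1611 without N-ZFP 1 and 2, and 6125 without N-ZFP 4.

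Genes changed by the transgene were set against those changed by each repressor. With N-ZFP in R6/2, 2543 of the 2841 called genes (89.5%) had the opposite call in R6/2 against NCAR under N-Delta, 1613 of them lower in R6/2 and higher with N-ZFP. Independent lists of these sizes would share 793 genes in opposite directions. In the 10 simulations of unchanged groups 0 genes were reversed. The covariance of the 2 changes over all genes was -0.0453 there, against -0.354 in the data. Simulated genes varied independently, without the structure between libraries seen in the data. The length index turned over these groups too, at -0.397 in NCAR N-Delta, 0.286 in R6/2 N-Delta and -0.051 in R6/2 N-ZFP. With it as a covariate 1565 genes were reversed. NCAR N-Delta also differed from NCAR A-Delta in 8057 genes, so part of the count may follow the libraries. Abhd11os went from -5.70 ± 0.27 to 3.66 ± 0.27, Ppp1r1a, a phosphatase inhibitor gene, from -1.88 ± 0.11 to 1.24 ± 0.10, Ciart, a clock repressor gene, from -1.96 to 1.59, Fst from -2.44 to 2.25 and Tpx2 from 2.14 to -1.41. Both comparisons use the R6/2 N-Delta libraries, and with those libraries split 2 and 2 between them 642 to 1026 genes were reversed, against at most 289 for independent lists. The 2543 became 5471 without N-ZFP 4, 1478, 1586 and 1566 without N-Delta 1, 2 and 4, and 1281 and 1404 without N-ZFP 1 and 2. In a pair of comparisons with no shared library, genotype calls under A-Delta and N-ZFP calls in R6/2 had opposite directions for 1654 genes, while 8 were higher and 21 lower in both (417 opposite for independent lists). Genotype calls of zQ175 bulk and N-ZFP calls in R6/2 gave 549 opposite, 38 higher in both and 23 lower in both (212 for independent lists). Genotype calls under A-Delta and N-ZFP calls in NCAR gave 696 opposite, 307 higher in both and 239 lower in both (694 for independent lists). With A-ZFP, 5 of 7 calls were reversed: Lcat (-1.18 to 1.04), Gja1 (-0.46 to 0.43), Sfrp5 (-1.71 to 1.57), Cd44 (-0.66 to 0.65) and Txlnb (0.49 to -1.59). With the A-Delta libraries split, 0 to 5 were, with a median of 0.5. Simulations reversed 0 here, with a covariance of -0.0433 against -0.0651 in the data. The 5 became 2, 1, 2, 3 and 3 without A-Delta 1, A-Delta 2, A-ZFP 1, A-ZFP 2 and A-ZFP 3. Txlnb fell with A-ZFP in NCAR as well, so its fall was not particular to R6/2.

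A genotype score per library, the mean log2 CPM of the genes higher in mutant mice minus that of the lower genes, used gene lists from libraries not being scored. In R6/2 it was -0.27 ± 0.087 (SD, n = 4) with N-Delta and -1.02 ± 0.115 (n = 4) with N-ZFP, a difference of -0.75 (exact two-sided permutation p = 0.0286, the smallest possible; adjusted p = 0.114 over 4 tests). NCAR libraries scored -1.931 ± 0.027 with N-Delta and -1.963 ± 0.049 with N-ZFP. With A-Delta and A-ZFP, scored on the list from the N-Delta libraries, R6/2 gave 1.416 ± 0.101 (n = 4) and 1.268 ± 0.111 (n = 3), a difference of -0.148 (exact permutation p = 0.114). The NCAR groups gave 0.525 and 0.562. The N-Delta list came from a comparison in which the length index differed by 0.683 between genotypes. In each A group the library lowest in the index also scored lowest, such as NCAR A-Delta 2 (index -0.25, score 0.151) and R6/2 A-ZFP 2 (-0.163, 1.14). The index averaged 0.121 in R6/2 A-Delta and 0.008 in R6/2 A-ZFP, so part of the difference of -0.148 may follow it. In zQ175 bulk libraries the difference with N-ZFP was -0.07 (exact permutation p = 0.114, n = 4 and 4), with zQ175 at -0.199 ± 0.023 and -0.269 ± 0.069 and WT at -1.025 and -1.063. In neuronal libraries it was 0.073 (exact permutation p = 0.629), with zQ175 at -0.313 ± 0.038 and -0.24 ± 0.316 and WT at -1.309 and -1.131. On another gene list the A-ZFP difference turned to 0.082 and the zQ175 bulk one to 0.002. On the 100 strongest genes per direction the zQ175 bulk difference was -0.125 (exact permutation p = 0.0286) and the neuronal one -0.22, and the neuronal one was -0.025 on all called genes and -0.191 without the high-mitochondria libraries. The zQ175 bulk difference was -0.104 without N-ZFP 1, and the neuronal one turned to -0.046 without N-ZFP 3.

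**Figure D2:**
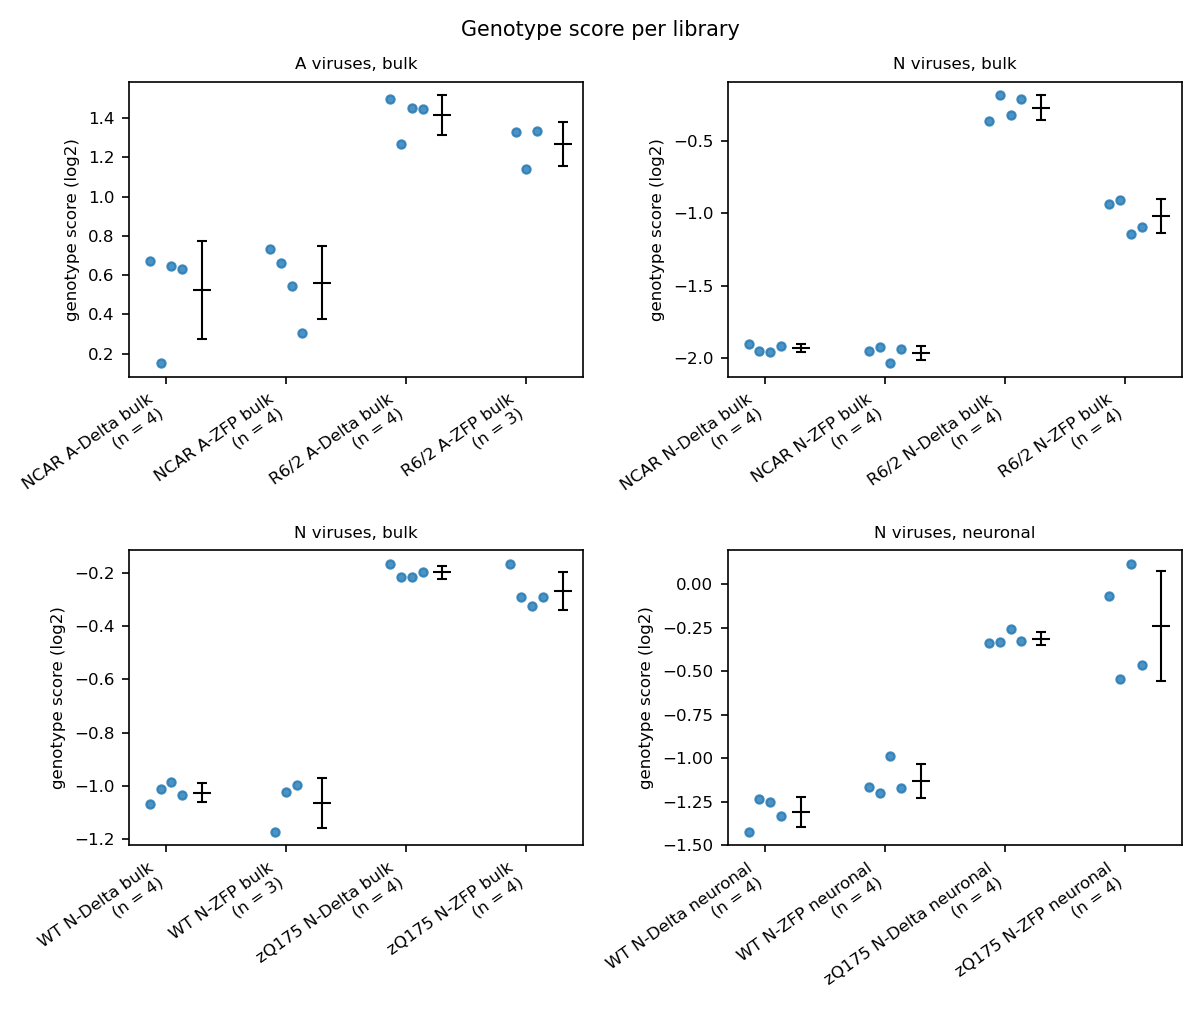
The genotype score of each library (y axis, log2 CPM units) by group (x axis) in 4 panels, with points for libraries and bars for the mean and SD. The R6/2 N-ZFP libraries average -1.02, between the R6/2 N-Delta mean of -0.27 and the NCAR N-Delta mean of -1.931.

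In NCAR (n = 4 and 4) N-ZFP raised 2563 genes and lowered 2213, but only 120 and 171 by at least 2-fold. Synaptic signalling genes rose in 22 of 49 cases, with Nlgn2 at 0.69, and nuclear oxidative phosphorylation genes fell in 47 of 75, with Uqcrh at -0.67 and Ndufb3 at -0.57. Each gave adjusted p = 0.793 with an estimated correlation (camera adjusted p = 1.18e-05 and 2.5e-17). Striatal neuron markers rose in 11 of 45 cases and fell in 2, with Bcl11b at 0.92 and Arpp21 at -0.77 (adjusted p = 0.907 with an estimated correlation), and vascular markers rose in 13 of 30, with Tie1 at 1.15. Adora2a rose by 0.71 ± 0.26 (adjusted p = 0.0496) and Pde10a by 0.79 ± 0.29 (0.0491), while Ppp1r1b at 0.49 ± 0.20 (0.0838) and Penk at 0.44 ± 0.21 (0.123) did not pass. Neither rise was called without the low-count filter, on the 2 groups alone or with the length index as a covariate. Nap1l3 fell by 1.69 ± 0.28 and Dnajc12, a co-chaperone gene, by 1.63 ± 0.22. The length index moved with these groups, at -0.044 ± 0.256 (SD) in N-ZFP against -0.397 ± 0.077 in N-Delta (difference 0.353, exact two-sided permutation p = 0.0857, n = 4 and 4). Fitted on the 2 groups alone, 32 genes were called, and with the length index as a covariate 30. Without N-Delta 1, N-Delta 4, N-ZFP 1, N-ZFP 3 and N-ZFP 4 the count was 40, 122, 153, 39 and 170. N-ZFP 4 held 45.9 CPM of the Y-linked gene Ddx3y against 114 to 119 in the other 3.

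The N-ZFP effect differed between R6/2 and NCAR in 7028 genes, 3700 higher and 3328 lower in R6/2. Pmch came first by the naming rule, but it held 2 counts in R6/2 N-Delta, and its level in R6/2 N-ZFP rested on libraries 1 and 2 (5.9 and 1.51 CPM). Abhd11os differed by 3.73 ± 0.34, Upb1 by 1.88, Arpp19, a phosphatase regulator gene, by 1.07, Pcp4 by 0.98 and Rgs4 by 0.85 ± 0.14, and Tceal6 by -2.23 ± 0.44. Nuclear oxidative phosphorylation genes were higher in 67 of 75 cases, with Ndufb4 at 1.53, and clustered protocadherins lower in 21 of 44. Each gave adjusted p = 0.562 with an estimated correlation, and these lists moved with the length index. Vascular markers were lower in 16 of 30 cases (adjusted p = 0.841 with an estimated correlation). The effect on Penk (0.35 ± 0.29, adjusted p = 0.368), Drd1 (0.44, 0.115), Ppp1r1b (0.18, 0.65), Adora2a (0.15, 0.771) and Pde10a (-0.13, 0.818) was not called as different. With the length index as a covariate 223 genes were called, and the count was 4671 and 4492 without NCAR N-Delta 1 and R6/2 N-ZFP 2.

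The ZFP effects in R6/2 were compared directly, N-ZFP over N-Delta minus A-ZFP over A-Delta. Among neuronal genes, these were higher with the N virus: Rasgrp2 by 1.41 ± 0.25, Scn4b by 1.92 ± 0.46 (adjusted p = 0.0293), Upb1 by 2.32 ± 0.36, Gabrd by 0.93 ± 0.15 and Oprk1 by 1.25 ± 0.22. The astrocyte genes Gja1, Aqp4 and Lcat were lower with it, Gja1 by -0.73 ± 0.10 (adjusted p = 0.00021), Aqp4 by -0.62 ± 0.14 (0.0252) and Lcat by -0.83 ± 0.20 (0.0343). So were the stress-response genes Hspa5 (-0.86 ± 0.13), Xbp1 (-0.55 ± 0.08) and Pdia6 (-0.64), and Penk at 0.95 ± 0.31 did not pass the test (0.146). In all 191 genes were higher and 75 lower. Of the lists, striatal neuron markers had 4 of 45 higher (16 higher and 1 lower adjusted over the list alone; camera adjusted p = 9.04e-10; adjusted p = 0.402 with an estimated correlation). Homeostatic astrocyte markers had 2 of 40 lower (6 lower and 1 higher over the list alone; adjusted p = 0.0685 with an estimated correlation), and stress-response genes 5 of 34 lower (11 over the list alone; 0.0444 with an estimated correlation). The count of 266 was 597 without N-ZFP 4 and 176, 135, 139, 177 and 176 without A-Delta 3, A-ZFP 1, A-ZFP 3, N-Delta 1 and N-Delta 2, and DESeq2 called 558.

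In zQ175 against WT bulk striatum under N-Delta (n = 4 and 4), projection neuron markers fell at 12 months: 42 of 45 striatal neuron markers were lower and 1 higher. Penk changed by -1.29 ± 0.06 (adjusted p = 1.55e-11), Scn4b by -1.86 ± 0.08, Cnr1, the cannabinoid receptor, by -1.45 ± 0.07, Pde10a by -1.35 ± 0.09, Drd1 by -1.02 ± 0.08, Drd2 by -1.03 ± 0.08 and Adora2a by -1.26 ± 0.09. Developmental transcription factors rose in 9 of 20 cases and fell in none: Wt1 went from 0.217 to 6.32 CPM (4.76 ± 0.40, 27.1-fold) and Shox2 from 0.409 to 14.4 CPM (5.07 ± 0.46). Hoxc4 averaged 4.38 CPM in zQ175 and had no counts in the 4 WT libraries, where 3 counts correspond to 0.268 to 0.346 CPM over the series. Gfap, the astrocyte filament gene, rose by 0.65 ± 0.15 (adjusted p = 0.00546). In all 1102 of 17114 genes rose and 1637 fell, with 78 and 250 changed at least 2-fold.

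Lists that held in zQ175 bulk with an estimated correlation were striatal neuron markers (adjusted p = 0.0126), indirect-pathway markers (9 of 13 fell, 0.000982), interneuron markers (10 of 19 fell, 0.0114), immediate early genes (18 of 28 fell, 0.0174), synaptic genes (32 of 49 fell, 0.0444) and developmental factors (0.000335). Examples were Gpr6 at -1.18, Homer1, a postsynaptic scaffold gene, at -0.96 ± 0.07, Itpr1 at -0.71 and Kit at -0.39. Interferon-response genes rose in 10 of 38 cases, with Irf7 at 1.22 ± 0.24 and Ifit1 at 1.04 (camera adjusted p = 1.55e-06; adjusted p = 0.258 with an estimated correlation), and microglial markers in 5 of 30, with Ctss at 0.45 and Trem2 at 0.39 (adjusted p = 0.403 with an estimated correlation). Reactive astrocyte genes rose in 6 of 26 cases and fell in 1, with Serpina3n at 0.60 and Vim at 0.51 (adjusted p = 0.384 with an estimated correlation). Homeostatic astrocyte markers fell in 9 of 40 cases and rose in 1, with Slc4a4 at -0.54 and Slc1a2 at -0.45 ± 0.12 (adjusted p = 0.514 with an estimated correlation), and cortical markers fell in 11 of 23, with Ccn2 at -1.42 (adjusted p = 0.392 with an estimated correlation). The lowest named genes were Gpx6, a glutathione peroxidase, at -4.57 ± 0.31, Sec14l3 at -3.55 and Ryr1 at -3.01 ± 0.15. With the R6/2 genotype calls under A-Delta, 553 higher and 1099 lower genes were shared and 21 had opposite calls, where independent lists would share 177 and 273.

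In neuronal libraries, zQ175 was compared with WT under N-Delta (n = 4 and 4). Striatal neuron markers fell in 39 of 45 cases and rose in none, with Scn4b at -2.15 ± 0.19, Penk at -1.72 ± 0.19, Adora2a at -1.57 and Pde10a at -1.41 ± 0.14 (adjusted p = 0.0334 with an estimated correlation). Synaptic genes fell in 25 of 49 cases (0.0346 with an estimated correlation) and immediate early genes in 10 of 26, with Homer1 at -1.06 and Egr2 at -2.78 (adjusted p = 0.177 with an estimated correlation). Developmental factors rose in 6 of 9 cases, with Wt1 at 4.77 ± 0.45 (4.03e-05 with an estimated correlation), and oligodendrocyte markers in 6 of 30, with Mog at 0.96 (adjusted p = 0.344 with an estimated correlation). In all 526 of 15815 genes rose and 954 fell, and 323 higher and 776 lower genes were shared with bulk, with none called in opposite directions by edgeR in both, where independent lists would share 36 and 97. These 2 sets of libraries are not taken as independent, since their sample numbers point to the same animals, although no label says so. The count of 1480 was 929 and 888 without WT N-Delta 1 and zQ175 N-Delta 2, and 3492 in a fit on the 2 groups alone.

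N-ZFP in zQ175 bulk striatum (n = 4 and 4) changed no gene by edgeR or by DESeq2, and 922 genes had an unadjusted edgeR p under 0.05. Penk was at -0.01 ± 0.06, Drd1 at 0.09 ± 0.08, Ppp1r1b at 0.05 and Gfap at -0.21 ± 0.15. Microglial and reactive astrocyte lists went down by camera (adjusted p = 1.07e-06 and 4.11e-05) with no member called, and gave adjusted p = 0.529 and adjusted p = 0.477 with an estimated correlation. In WT bulk (n = 3 and 4) edgeR called no gene, DESeq2 21, and 1384 had an unadjusted edgeR p under 0.05. Cortical excitatory markers had a median of -0.50 in WT, with 5 of 23 lower adjusted over the list alone (adjusted p = 0.893 with an estimated correlation). The difference between zQ175 and WT reached the threshold for no gene by edgeR or by DESeq2 (607 at an unadjusted edgeR p under 0.05). Without zQ175 N-ZFP 2 in the first case, and without WT N-Delta 4 or WT N-ZFP 1 in the second, 1 gene was called. Without a low-count filter 41 genes were called in zQ175, 73 in WT and 12 for the difference.

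In neuronal libraries N-ZFP lowered 31 genes and raised 21 in zQ175 (n = 4 and 4). Tceal6 fell by 1.44 ± 0.13 (adjusted p = 0.000101), Nap1l3 by 1.25 ± 0.16, Lysmd2 by 1.20 ± 0.12, Atp2b3 by 1.06 ± 0.16 and Nptx2, a neuronal pentraxin gene, by 0.91 ± 0.15. Bmp7, a bone morphogenetic protein, rose by 1.15 ± 0.18, Wnt7a by 0.98, Stc1 by 1.11 and Grm3, a metabotropic glutamate receptor, by 0.60. Of the 52 calls, 17 were opposite to the zQ175 genotype calls, among them Bmp7 (-2.10 to 1.15), Fst (-3.06 to 1.55), Hrh3 (-1.07 to 0.52) and Fat1 (0.99 to -0.55). With the zQ175 N-Delta libraries split between the 2 comparisons none was reversed. The simulations of unchanged groups reversed 0 genes. Their covariance of the 2 changes over all genes was -0.0431, against -0.0416 in the data. Over all genes the opposition was thus no larger than the shared libraries alone gave. The panel did not pass the test (Penk 0.10 ± 0.18, Drd1 0.19, Pde10a 0.29). Mitochondrially encoded genes were called in none of 10 cases over all genes and in 10 adjusted over the list alone, all higher, and microglial markers in 7 of 20. Both gave adjusted p = 0.62 with an estimated correlation. N-ZFP libraries 1 and 3 of zQ175 held 1.20% and 1.97% of counts in mitochondrial protein-coding genes, and those of WT 0.338% and 0.512%. Without these 4 libraries 180 genes were called in zQ175 and 81 were reversed, with Penk then rising by 0.44 and Drd1 by 0.41, and DESeq2 called 1792 with all libraries. With the replicate number as a block 883 genes rose and 370 fell (1253 in place of 52), 128 of them reversed, and with length and GC offsets 11 rose and 34 fell. The 52 was 17, 22, 25 and 20 without N-Delta 1 to 4, and 22, 4348 and 3431 without N-ZFP 1, 2 and 4, and the 17 reversed became 1, 2, 4 and 2, then 1, 207 and 185. Without N-ZFP 2 or 4 the high-mitochondria libraries 1 and 3 made up most of the group, so those large counts may follow these libraries.

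In WT neuronal libraries (n = 4 and 4) N-ZFP lowered 15 genes and raised 5. Tceal6 fell by 1.55 ± 0.13, Mzt2 by 1.54 ± 0.17, Myo3b by 1.23 ± 0.20 and Dach1 by 1.16 ± 0.17, and Htr2a, a serotonin receptor gene, rose by 0.87 ± 0.13 and Egfr by 0.42. Homeostatic astrocyte markers went down by camera (adjusted p = 2.79e-11; adjusted p = 0.315 with an estimated correlation). The zQ175 and WT effects did not differ for any gene by edgeR or DESeq2 (739 at an unadjusted edgeR p under 0.05). With the replicate number as a block 33 genes were called in WT, and with offsets 1 rose and 14 fell. The WT count was 11 to 13 without any one N-Delta library and 40, 10 and 9 without N-ZFP 2, 3 and 4. The N-ZFP effect in zQ175 differed between neuronal and bulk libraries for 11 genes, all lower in neuronal RNA, with Tceal6 at -1.44 ± 0.18, Lysmd2 at -1.19, Dnajc12 at -1.16, Nap1l3 at -1.11 and Dach1 at -1.04. That count was 2 to 7 without bulk N-Delta 1, 3 or 4, bulk N-ZFP 1, 3 or 4, or neuronal N-Delta 1, 2 or 4, 1731 and 1103 without neuronal N-ZFP 2 and 4, and 20 with the animal as a block, taking bulk and neuronal libraries of the same number as 1 animal. Without neuronal N-ZFP 2 or 4, high-mitochondria libraries again made up most of that group.

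The N-ZFP calls were compared over 6 sets of separate libraries: R6/2, NCAR, and zQ175 and WT in bulk and in neuronal RNA. Of 15603 genes tested in all 6, 17 fell in at least 3, where 0.364 would for independent lists, and 9 fell in 4. That value ignores that neuronal N-ZFP libraries of zQ175 and WT with the same number correlated. It also ignores that bulk and neuronal numbers point to the same animals. The rule of at least 3 was chosen after the tables were seen. Tceal6 fell by 3.54, 1.31, 1.44 and 1.55 in R6/2, NCAR, zQ175 neuronal and WT neuronal libraries, and Nap1l3 (chromosome X, 122394565 to 122397401) by 2.97, 1.69, 1.25 and 1.17. Atp2b3 (chromosome X, 73503086 to 73571005) fell by 2.98, 1.12, 1.06 and 1.06, and Dach1 (chromosome 14, 97786853 to 98169765) by 2.35, 0.64, 1.02 and 1.16. Dnajc12, Mzt2, Impdh1, which makes guanine nucleotides, Lysmd2 and Acsl1, an acyl-CoA synthetase, also fell in these 4. Eid2b, Noa1, Rsl24d1, Fkbp3, St6galnac5, Kcna6, Opcml and Ndrg3 fell in 3. Of the 17, 15 were called in NCAR, 6 with the length index as a covariate and 4 on the 2 groups alone, where Tceal6, Atp2b3 and Dach1 were not called in either. With the covariate 11 genes fell in at least 3 sets and 5 in 4, and with each comparison fitted on its 2 groups alone 5 and 0. In the bulk zQ175 and WT libraries the changes were small and not called, with Tceal6 at -0.07 and -0.07 and Nap1l3 at -0.20 and -0.22. The genes higher in 3 comparisons were Gpr83, Hrh3, Htr2a and Stc1, where 0.387 would be for independent lists. Tceal6 and Nap1l3 were lower in R6/2 than the A-ZFP effect, with N minus A differences of -3.39 and -2.85.

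**Figure D3:**
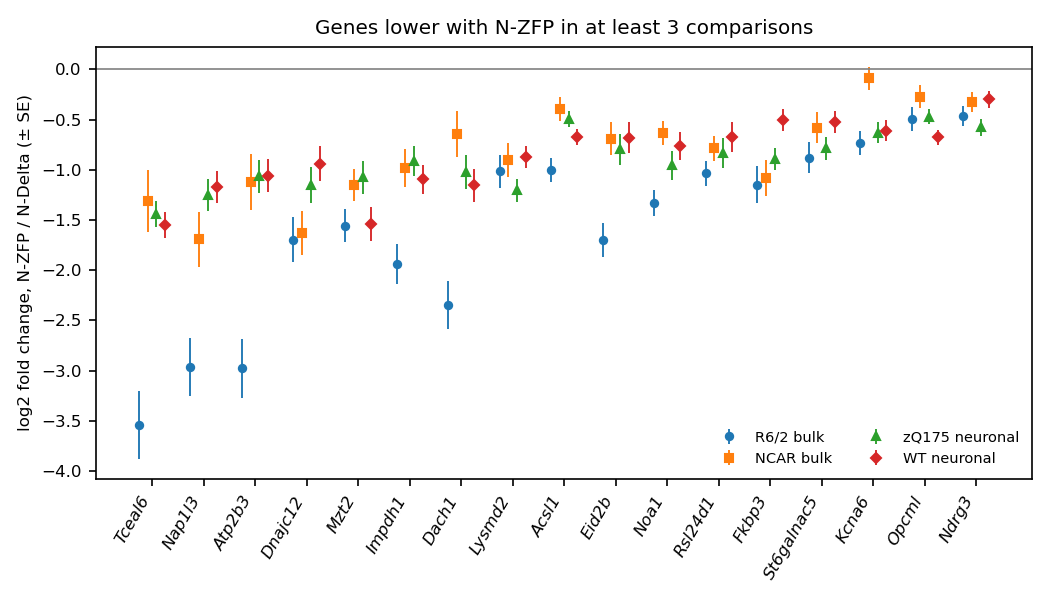
The log2 fold change of N-ZFP over N-Delta with its SE (y axis) for the 17 genes that fell in at least 3 of 6 comparisons (x axis), with 1 point for each of 4 sets of libraries. Tceal6 is lowest in R6/2 bulk, at -3.54, and lies between -1.31 and -1.55 in the other 3 sets.

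Neuronal RNA was compared with bulk RNA of WT mice given N-Delta (n = 4 and 4) to see what the neuronal libraries hold. Striatal neuron markers were higher in 39 of 45 cases and lower in 1, with Penk at 1.12 ± 0.15, Ppp1r1b at 0.95 and Drd1 at 0.50 (camera adjusted p = 1.89e-13; adjusted p = 0.172 with an estimated correlation). All 30 microglial markers were lower, with C1qa at -6.31 (adjusted p = 0.0671 with an estimated correlation). Homeostatic astrocyte markers were lower in 37 of 40 cases and higher in 1, with Slc1a2 at -1.49 and Aqp4 at -1.70 (adjusted p = 0.0671 with an estimated correlation). Oligodendrocyte markers were lower in 28 of 30 cases, with Mbp at -1.85 (adjusted p = 0.103 with an estimated correlation), and vascular markers in 28 of 30, with Pecam1 at -4.31 (0.00247 with an estimated correlation). All 12 mitochondrially encoded genes were lower (adjusted p = 0.172 with an estimated correlation). Rpl22, a ribosomal protein gene, was higher by 1.57 ± 0.56. In all 4652 of 17702 genes were higher and 5237 lower, and with length and GC offsets 6683 and 4055.

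Huntingtin itself was read from the mouse gene Htt, whose counts do not separate the alleles, and a human transgene cannot be counted on mm10. In zQ175 against WT, Htt changed by -0.47 ± 0.08 (adjusted p = 0.000343) in bulk and by -0.56 ± 0.10 (0.00166) in neuronal RNA. In R6/2 against NCAR it was at -0.10 ± 0.15 (0.651) under A-Delta and rose by 0.65 ± 0.15 (0.000565) under N-Delta. With N-ZFP it was at -0.28 ± 0.15 (0.194) in R6/2, 0.40 ± 0.15 (0.0512) in NCAR and 0.10 ± 0.08 in zQ175 bulk, none of which passed the test. Nor did it pass at -0.07 ± 0.10 (0.669) in zQ175 neuronal, -0.04 ± 0.10 in WT neuronal or 0.03 ± 0.08 in WT bulk libraries. The R6/2 and NCAR effects of N-ZFP on Htt differed by -0.68 (adjusted p = 0.0161). With length and GC offsets this difference was -0.05 and the rise under N-Delta 0.06, and with the length index as a covariate -0.06 and 0.02, with no call in either.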

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

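The counts over other splits of the libraries and the tests of the NCAR pattern were chosen only after the results were seen. The N-ZFP effect differed between R6/2 and NCAR in 7028 genes by the test of the difference itself, but in only 223 with the length index as a covariate. Abhd11os differed by 3.73 ± 0.34 and Rgs4 by 0.85 ± 0.14, both higher in R6/2, and Tceal6 by -2.23 ± 0.44. Within R6/2 the effects of the N and A repressors differed in 266 genes, with Upb1 at 2.32 ± 0.36 and Gja1 at -0.73 ± 0.10 for N minus A. In zQ175 the N-ZFP effect differed between neuronal and bulk libraries in 11 genes, all lower in neuronal RNA, with Tceal6 at -1.44 ± 0.18.

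The N-ZFP calls in NCAR moved with the length index: 4776 genes were called with a median change of 0.459 (quartiles 0.346 to 0.617) in the direction of the call. With offsets for transcript length and GC content 1967 of these calls were kept (2668 calls in all), and the median change over all 4776 fell to 0.292 (0.162 to 0.447), so a trend with either stays open as the source of the others. A difference in library size is argued against, since with the 8 libraries thinned to the same total 4390 of the calls were kept and the median change was 0.456 (0.345 to 0.613). With the index itself as a covariate 29 were kept (30 calls in all) and the median change was 0.214 (0.152 to 0.318), so another difference between libraries that the index marks may account for many of the calls. The bound for that test was set after the count was seen and was met narrowly, the index partly follows the virus (0.353, exact two-sided permutation p = 0.0857, n = 4 and 4), which by itself widens the errors, and an effect of N-ZFP without the transgene stays open.

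Other splits of the same libraries, each refitted on the groups compared, gave as many called genes as the real split in only 1 of 35 cases, the real one, for R6/2 against NCAR under A-Delta (6493 genes, highest other split 6) and under N-Delta (11014, 3), for N-ZFP in R6/2 (712, 5), for zQ175 against WT in bulk (2424, 0) and in neuronal libraries (3492, 0), for N-ZFP in zQ175 and WT neuronal libraries (7, 0 and 27, 0) and for neuronal against bulk RNA (9893, 0). For the differences it was 1 of 25 splits for N-ZFP between R6/2 and NCAR (4428, 63), for N minus A in R6/2 (219, 141) and for neuronal minus bulk in zQ175 (17, 12). In these last 3 the highest other split exchanged or kept the whole groups of 1 of the 2 effects, which keeps that effect, and without such splits the highest was 9, 1 and 0. In each of these the real split came first, the smallest share that 35 or 25 splits allow, unadjusted over the 19 comparisons. So few splits cannot exclude chance for a single count or gene. Chance is argued against where the real count was at least 712 and no other split passed 6. For A-ZFP at least as many genes were called in 9 of 35 splits in R6/2 (real 2, highest other 4) and in 4 of 35 in NCAR (real 4, highest other 9). For N-ZFP in NCAR it was 2 of 35 (real 32, highest other 6099). That other split set N-Delta 1, 3 and 4 and N-ZFP 2 against the rest, which follows the first principal component (-68 to -44.5 against -37.1 to -19.8) and points to a structure of the samples. For N-ZFP in WT bulk (6 of 35, real 1, highest other 423) other splits called many more genes than the real one, which points to a structure of the samples too. A real count of 0 cannot be tested this way, as all splits reach it: this holds for N-ZFP in zQ175 bulk, where another of the 35 splits called 85 genes, and for the differences of the A-ZFP effects and of the N-ZFP effects in zQ175 and WT, in bulk and in neuronal libraries (25 splits each, highest other 0, 2 and 0).

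Single libraries lay far from the other 3 of their group in 17 of 217 groups of 4 values, where chance gives about 10.8, or 1 in 20. Expression of panel genes stood apart for Kcnj10 in R6/2 A-Delta 4 (96 CPM, others 39.1 to 45.4), Penk in NCAR A-Delta 3 (910.5, others 714 to 731), Drd2 in WT N-Delta bulk 1 (119 CPM, others 93.1 to 97.5) and Htt in NCAR A-Delta 2 (210.3, others 267 to 277) and zQ175 N-Delta neuronal 3 (337.5, others 261 to 272). In zQ175 N-ZFP bulk 1, Gfap was low at 120.9 CPM (others 169 to 178), and Slc1a2 at 3925 (2800 to 2963) and Kcnj10 at 112.1 (82.5 to 86.4) were high. The length index of that library was 0.341 (others -0.209 to -0.117). The index also stood apart in NCAR A-Delta 2 at -0.25 (0.176 to 0.239), R6/2 N-Delta 1 at 0.381 (0.241 to 0.262) and WT N-Delta neuronal 4 at -0.215 (-0.117 to -0.115). Genotype scores did in NCAR A-Delta 2 at 0.151 (0.631 to 0.672), WT N-ZFP neuronal 3 at -0.988 (-1.199 to -1.165) and zQ175 N-Delta neuronal 3 at -0.256 (-0.339 to -0.325). Total counts were highest in R6/2 N-Delta 1 at 67.63 M (63.2 to 63.8) and zQ175 N-ZFP bulk 2 at 9.48 M (8.66 to 8.72).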

How the results depend on the processing

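The R6/2 and zQ175 genotype counts under A-Delta and in bulk, the neuronal over bulk count and the N-ZFP score in R6/2 stayed within 1.5 times their value under every alternative run, while repressor counts depended on the choices below, where the cause was not tested unless stated. The length and GC offsets, the length index covariate and leaving out the high-mitochondria libraries were chosen after seeing the data. A term for sex was not run, since all libraries had Y-linked and no appreciable Xist counts, although NCAR N-ZFP 4 held 45.9 CPM of Ddx3y against 114 to 119 in the rest of its group, with the other Y-linked genes lower too. In zQ175 N-ZFP bulk 2 Y-linked genes were high, at 391.8 CPM in sum (others 246.8 to 277.5). Neuronal library 2 of that group held 179.5 CPM of Ddx3y (others 101.5 to 123.8), while its sum of 317 was below the 342.3 of library 3. With the DESeq2 Wald test, A-ZFP in R6/2 gave 21 genes and 14 reversed, N minus A 558, N-ZFP in WT bulk 21, in zQ175 neuronal libraries 1792 with 145 reversed, in WT neuronal libraries 68, and neuronal minus bulk 97 (7 with DESeq2 size factors alone). Without the low-count filter, N-ZFP gave 41 genes in zQ175 bulk, 73 in WT bulk, 12 for their difference, 143 in zQ175 neuronal libraries and 24 for neuronal minus bulk, and the neuronal genotype count was 968. With the replicate number as a block, N-ZFP gave 1253 genes in zQ175 neuronal libraries with 128 reversed, 33 in WT neuronal libraries and 20 for neuronal minus bulk, and A-ZFP 3 reversed. Fitted on the groups compared alone, with a spread estimated from fewer libraries, A-ZFP in R6/2 gave 2, N-ZFP 712 in R6/2, 32 in NCAR and 4428 for their difference, 1 in WT bulk and 7 in zQ175 neuronal libraries, neuronal minus bulk 17, and the neuronal genotype comparison 3492. Offsets gave 11 for A-ZFP in R6/2, 2668 for N-ZFP in NCAR and 7 reversed in neuronal libraries. The covariate gave 15 for A-ZFP in R6/2 with 10 reversed, 4911 for the genotype under N-Delta, 30 for N-ZFP in NCAR, 223 for its difference from R6/2, 533 for N minus A and 1565 reversed by N-ZFP in R6/2. Without the high-mitochondria libraries the neuronal genotype count was 3727, N-ZFP gave 180 in zQ175 with 81 reversed, 55 in WT, 2 for their difference and 34 for neuronal minus bulk. With the Delta libraries split, median reversed counts were 0.5 for A-ZFP and 824.5 for N-ZFP in R6/2 and 0 in neuronal libraries, with fewer libraries per group. Scores turned for A-ZFP to 0.082 and for zQ175 bulk to 0.002 on another list, and for neuronal libraries to -0.025 on all called genes, -0.22 on the 100 strongest per direction and -0.191 without the high-mitochondria libraries. On the 100 strongest genes the zQ175 bulk score fell by 0.125 (exact permutation p = 0.0286). Of 333 gene values named in the report, 67 lost their call on the groups compared alone, 15 without the filter, 16 with offsets, 26 of 202 with the covariate and 291 of 2891 over all omissions of a replicate, and 0 reversed. Of 475 list tests, 184 lost their call and 32 kept one with an estimated correlation, and 0 reversed. Leaving out each replicate gave 2 to 9 genes for A-ZFP in R6/2 (1 to 6 reversed), 1407 to 6125 for N-ZFP in R6/2 (1281 to 5471 reversed), 39 to 7159 in NCAR, 4492 to 9451 for their difference, 135 to 597 for N minus A, 0 to 1 in zQ175 and in WT bulk, 888 to 1178 for the neuronal genotype, 17 to 4348 for N-ZFP in zQ175 neuronal libraries (1 to 207 reversed), 9 to 40 in WT and 2 to 1731 for neuronal minus bulk. The highest counts for N-ZFP in zQ175 neuronal libraries and for neuronal minus bulk came without zQ175 N-ZFP 2. That left high-mitochondria libraries as most of its group. Scores ranged from -0.104 to -0.051 in zQ175 bulk and from -0.046 to 0.175 in neuronal libraries. The 17 genes lower with N-ZFP in at least 3 sets became 5 on the groups compared alone, 11 with the covariate, 26 with the DESeq2 Wald test and 27 without the high-mitochondria libraries. Of 100 simulated 1.5-fold changes 41 to 42 were recovered in neuronal libraries and 66 to 75 in bulk, and the reason was not tested.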

Other observations

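Of the tests in this part, those of the neuronal libraries left out and of the CAG and CTG runs were set before their results were seen, and all others after. In the neuronal against bulk comparison of WT mice all 5 blood markers were lower, with a median of -4.63, and interferon-response genes were lower in 23 cases. The list tests of these 2 groups are not given here. The mitochondrial ribosomal RNA mt-Rnr1 was at -6.50 and the microglial protease gene Ctss, one of the listed markers, at -6.59. The protein kinase gene Prkcb was higher in neuronal RNA at 0.94. In zQ175 bulk striatum, stress-response genes were called in both directions (3 of 34 rose and 4 fell), with Trib3 at -1.88, and clustered protocadherins too, with Pcdhb2 at 1.08 and Pcdhga8 at -0.48 (13 of 43 rose and 6 fell; adjusted p = 0.551 with an estimated correlation). Of 12 mitochondrially encoded genes 4 fell, with mt-Atp6 at -0.50 (adjusted p = 0.311 with an estimated correlation), and Enpp6, a gene of newly formed oligodendrocytes, rose by 0.75.

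Genes called in zQ175 against WT bulk were followed in the R6/2 series as lists, which is not independent evidence of their direction in zQ175. Of the 283 genes higher in zQ175, 162 rose and 4 fell in R6/2 under A-Delta (3.7e-06 with an estimated correlation), and of the 768 lower genes 567 fell and 3 rose (0.00234). With N-ZFP in R6/2 the higher list gave 9 up and 47 down (0.0245 with an estimated correlation) and the lower list 231 up and 11 down (adjusted p = 0.516 with an estimated correlation). In N minus A the lower list gave 63 up and none down, and the higher list none up and 3 down (adjusted p = 0.178 and 0.0417 with an estimated correlation). Lists from R6/2 behaved alike in zQ175 bulk: 163 of 607 higher genes rose and 2 fell, and 482 of 1085 lower genes fell and 3 rose (0.000335 and 1.26e-05 with an estimated correlation).

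The 17 genes that fell with N-ZFP in at least 3 of 6 sets of libraries, in mice with and without mutant Huntingtin, were examined for a shared feature. With length and GC offsets 16 of them were still called lower in R6/2. Without the high-mitochondria libraries 17 had a log2 fold change below -0.25 in zQ175 neuronal libraries. All 17 had been picked through calls in these same 2 comparisons, so neither check can exclude such a source. In NCAR 15 were called, 17 with the offsets and 6 with the length index as a covariate. A run of at least 6 CAG or CTG units stood in an annotated transcript of 5 of the 17 (29.4%), against 270 of 15531 other genes (1.74%; Fisher's exact test p = 8.68e-06, odds ratio 23.5 with a 95% interval of 6.45 to 72.4). None of 10000 draws of genes matched on length and expression held 5 (mean 0.33, highest 4). A candidate explanation is that the repressor binds such runs, which Nap1l3 (8 CAG), St6galnac5 (11 CAG), Kcna6 (9 CTG), Tceal6 (6 CTG) and Dach1 (6 CAG) carry, but 12 of the 17 lack one, binding was not measured, and other properties of these genes stay open.

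N-ZFP libraries 1 and 3 of both genotypes stood apart in neuronal RNA by their mitochondrial share, and in zQ175 they differed from N-ZFP 2 and 4 by 3.68 for mt-Nd5, 2.83 for Malat1 and 2.86 for Meg3 (log2). Bulk striatal RNA carried over is argued against by homeostatic astrocyte and oligodendrocyte markers, whose medians were -0.187 and -0.315 although bulk holds them at higher levels. Long intergenic RNAs had a median of 1.062 and protein-coding genes of -0.064, a difference of 1.126, and in WT 0.292 and -0.025. That may point to RNA not bound to ribosomes carried over. Bulk also held more long intergenic RNA than neuronal libraries (median log2 difference 0.623), so this excess alone does not tell unbound from bulk RNA. Microglial markers at 2.08 and oligodendrocyte precursor markers at 1.16 rose with the long intergenic RNAs. The groups of 2 libraries were formed by their mitochondrial share, and a difference between the animals stays open.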
